A study of Homo sapiens with 20 samples.

How the data were processed

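Total RNA of IMR90 cells in 16 conditions (4 states by 4 hairpins) was measured on 20 arrays, 2 for each day 7 condition and 1 for each other condition. Per the labels, RNA was extracted with RNeasy columns, and 1 µg was amplified with MessageAmp II into biotin-labelled cRNA and hybridised by the Affymetrix protocol. The authors' deposited table holds log2 values, background corrected, normalised between arrays and summarised per probe set. GCRMA is the only tool that the processing notes name, and its version is not given in the sources used here. The values ran from 1.87 to 14.65 and the columns had nearly the same quartiles, which was checked on the table. No genome build is given in the sources used here, so no coordinates are printed. Whether day 7 duplicates were separate cultures is not given either, and the growth protocol and the titles differ on the day of the day 3 arrays.

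Of 32321 probe sets, 19158 had 1 gene symbol, 1388 had several and 11775 had none in the annotation used here, and the last 2 kinds were not analysed. Symbols were updated through Entrez identifiers, of which 19128 matched the RefSeq table of GRCh38.p14 and 30 kept their symbol. Where a gene had several probe sets (637 of 18404 genes), the probe set with the highest mean was used. Genes with a log2 value above 4 in at least 2 arrays were kept, which removed 538 and left 17866. Array values carry no counts, so no depth or counting interval applies.

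Models were fitted with limma 3.58.1 in R 4.3.3. The state comparisons and the hairpin effects over the states came from a fit of the 16 condition values, with duplicates averaged, on state and hairpin (9 residual and 4.93 prior degrees of freedom). There the 4 hairpin lines, or the 4 states, served as matched sets, and any interaction of state and hairpin counted as spread. The day 7 hairpin comparisons used the 8 day 7 arrays (4 residual and 5.40 prior degrees of freedom). The interaction of shtandem with state used all 20 arrays in 16 groups, in which only the day 7 duplicates give the spread and the single arrays are assumed to vary like them. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes in each of 14 comparisons, with calls at an adjusted p under 0.05. Intervals of remaining target level are 95% intervals of the limma estimate.

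The lists were fixed, with the comparisons, filter, gene rule and settings to vary, before the data were examined. They were 21: DNA replication, G1/S and E2F target genes, mitosis, secretory phenotype of senescence, p53 targets, RAS and MAPK output, senescence regulators and markers, extracellular matrix, contractile and SRF genes, immediate early genes, FOXO targets and growth arrest, cholesterol synthesis, interferon-induced genes, lysosome and autophagy, unfolded protein and stress response, oxidative phosphorylation, ribosome biogenesis, H3K4 methylation enzymes, and epithelial, endothelial and immune cell markers. Each was tested against all other genes with camera in limma at a preset correlation between genes of 0.01, adjusted over the 21 lists, and again with the correlation estimated from the residuals. For every list past the threshold, the median, the mean and the test had the same sign. Named genes were KDM5A, KDM5B, HRAS, RB1, CDKN1A, CDKN2A, CDKN2B, LMNB1, CCNA2, PCNA and CCND1 in every comparison, up to 8 genes per direction with the largest change that were called with the same sign in every matched pair, and up to 3 per list. The same sign in every pair was thus a condition for naming the genes of largest change and gives no further support. Where no gene was called, the 3 per direction with the smallest p were named. FAM107B, clock genes other than those in the rule, and the genes of families chosen later are exceptions, named after their values were seen.

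Overlaps of called genes were set against independent lists, against simulated data with the same shared control arrays and no effect (1 set for r and covariance, and for the overlaps the mean of 20 sets, with as many genes as were called, by smallest p), and against comparisons that used different control arrays. The fits were tested on simulated data with known changes of 0.5, 1 and 2 log2 units in 67, 67 and 66 genes. The settings varied were no filter, a filter at log2 above 6, the mean of all probe sets, each array centred on its median gene, limma-trend, all 20 arrays entered separately, shLuc alone, the replicate number as a block, and leaving out each hairpin line, state or day 7 array. After the data were examined, 4 arrays with an interquartile range under 3.8 were left out or the range was entered as a covariate, and 12 gene families and a list of circadian clock genes were examined, the H3K4 list was tested without KDM5A and KDM5B, and list means at day 7 were taken for the first and the second arrays separately. The families were tested with camera and adjusted over the 12.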

Results

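Gene expression was measured on 20 microarrays in IMR90 cells, human fetal lung fibroblasts, in 4 states and with 4 retroviral short hairpins. The states were growing, quiescent after serum removal, and senescent after expression of activated HRAS, at day 3 and at day 7. The hairpins were shLuc, which targets luciferase and served as the control, shJarid1a, which targets KDM5A, shJarid1b, which targets KDM5B, and shtandem, which targets both genes. KDM5A and KDM5B, also called Jarid1a and Jarid1b, remove methyl groups from lysine 4 of histone H3. Each of the 16 conditions had 1 array, except the 4 day 7 conditions, which had 2. The titles name day 3 for 4 of the senescent arrays, whereas the growth protocol in the labels gives day 7 for all RNA, and the day in the title was used. The number of arrays limits the precision, and the p-values measure the spread between these samples only. At day 7 the median SD between duplicates was 0.11 log2 units in shLuc, 0.13 in shJarid1a, 0.08 in shJarid1b and 0.07 in shtandem. The interquartile range of the values on an array was 3.84 to 3.93 in 16 arrays and narrower in the other 4, all from senescent cells. These were the day 3 shLuc array (3.796), the day 3 shJarid1b array (3.77), the second day 7 shLuc array (3.77) and the second day 7 shJarid1a array (3.73).

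The first question was how far each hairpin lowered its target. Over the 4 states shJarid1a lowered KDM5A to 30.6% of the shLuc level (95% interval 26.1 to 35.9%, adjusted p = 4.77e-06), and shJarid1b lowered KDM5B to 27.8% (24.3 to 31.9%, adjusted p = 2.04e-07). The shtandem hairpin lowered KDM5A to 46.5% (39.6 to 54.6%, adjusted p = 4.33e-04) and KDM5B to 48.1% (42.0 to 55.2%, adjusted p = 2.23e-04). In each state, KDM5A with shJarid1a stood at 24.7 to 37.5% of shLuc, and KDM5B with shJarid1b at 22.6 to 35.01%. KDM5B with shtandem was 0.79 log2 units above its level with shJarid1b (SE 0.09, adjusted p = 0.00563), and KDM5A with shtandem was 0.60 above its level with shJarid1a (SE 0.11, adjusted p = 0.142). Neither demethylase passed the test with the hairpin against the other: KDM5A was at 96.0% with shJarid1b (81.8 to 113%, adjusted p = 0.926) and KDM5B at 90.9% with shJarid1a (79.3 to 104%, adjusted p = 0.668). Each of the 2 genes had 1 probe set, so these values rest on that probe set alone.

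**Figure D1:**
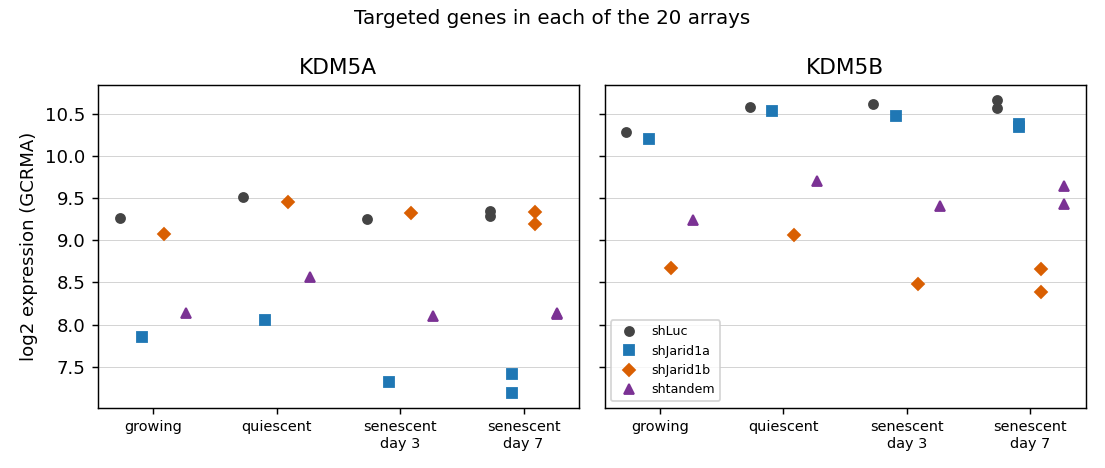
KDM5A and KDM5B levels on each array (vertical axis, log2 units) by state (horizontal axis), with 1 point per array and the hairpin shown by colour. KDM5A with shJarid1a lay between 7.19 and 8.06 and with shLuc between 9.25 and 9.52. KDM5B with shJarid1b lay between 8.39 and 9.06 and with shLuc between 10.29 and 10.67.

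The comparison of senescent day 7 with growing cells asked what changed with established senescence, over the 4 hairpin lines. The inflammatory cytokines IL1B and IL1A rose by 7.14 (SE 0.17) and 6.42 (SE 0.12) on the log2 scale. Mean log2 levels were 12.75 ± 0.21 (SD, n = 4 lines) against 5.60 ± 0.12 for IL1B, and 11.43 ± 0.13 against 5.01 ± 0.06 for IL1A. MMP3, a matrix metalloproteinase, rose by 6.65, CXCL8, a neutrophil chemokine, by 5.86, TNFSF15, a cytokine of the TNF family, by 5.96, and GABRA2, a GABA receptor subunit, by 5.75. ATP6V0D2, a subunit of the vacuolar proton pump, rose by 5.25 and CST1, a cysteine protease inhibitor, by 5.04. Genes that fell included the receptor tyrosine kinase KIT (-4.53), the muscarinic receptor CHRM2 (-4.61), SLC7A14 (-4.61), the secreted matrix protein RELN (-4.27), PLPPR4 (-4.22) and CEMIP, which takes part in hyaluronan breakdown (-4.10). These 14 changes had adjusted p from 2.05e-15 to 9.16e-09, and each had the same sign in 4 of 4 lines, as the naming rule required. HRAS itself rose by 1.91 (SE 0.06, adjusted p = 3.27e-12), CDKN2B, a CDK inhibitor, by 2.60, CDKN1A by 0.84 and CDKN2A by 0.46. LMNB1, a nuclear lamina protein lost in senescence, fell by 2.15. RB1 (log2 change -0.0041, adjusted p = 0.975), CCND1 (0.04, adjusted p = 0.481), KDM5A (-0.08, adjusted p = 0.609) and KDM5B (0.16, adjusted p = 0.188) did not pass the test, although KDM5B passed at 0.26 without the shJarid1b line (adjusted p = 0.0125).

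At day 7 the genes of cell division were lower than in growing cells. All 34 mitosis genes fell (median -2.70, list adjusted p = 6.19e-25, and adjusted p = 0.103 with an estimated correlation), among them CDK1 (-4.06), DLGAP5 (-4.10) and KIF20A (-3.87). Of 38 DNA replication genes 31 fell and 1 rose (median -0.75, adjusted p = 1.47e-12, and adjusted p = 0.117 with an estimated correlation), with TYMS at -2.36, RRM2 at -2.23 and PCNA, the sliding clamp, at -0.44. Of 30 G1/S and E2F target genes 24 fell and 2 rose (median -0.83, adjusted p = 4.15e-09, and adjusted p = 0.117 with an estimated correlation). CCNA2 fell by 3.19, whereas E2F7, an atypical E2F that represses transcription, rose by 2.75. The replication-dependent histone gene H3C11 fell by 4.13, though whether its probe set measured the histone mRNA or another transcript was not tested. With p adjusted over the list alone, 32 DNA replication genes fell, and the mitosis and G1/S counts were the same.

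Genes of the secretory phenotype, of RAS signalling and of p53 were higher at day 7 than in growing cells. Of 28 secretory genes 23 rose and 3 fell (median 2.06, adjusted p = 3.2e-12, and adjusted p = 0.0782 with an estimated correlation). Of 22 genes of RAS and MAPK output 18 rose and 2 fell (median 0.61, adjusted p = 6.21e-08), including the MAPK phosphatases DUSP4 (2.11) and DUSP6 (1.70). This call held with an estimated correlation (adjusted p = 0.0395). Of 22 p53 targets 13 rose and none fell (median 0.28, adjusted p = 2.57e-04, and adjusted p = 0.117 with an estimated correlation), with the secreted factor GDF15 at 2.32 and the kinase PLK3 at 1.63. Of 20 ribosome biogenesis genes 17 rose and 2 fell (median 0.40, adjusted p = 6.96e-06, and adjusted p = 0.127 with an estimated correlation), with POLR1B, a subunit of RNA polymerase I, at 1.07. Of 22 lysosome and autophagy genes 10 rose and 2 fell (median 0.08, adjusted p = 0.0131, and adjusted p = 0.319 with an estimated correlation), among them the cholesterol transporter NPC1 (2.14), the protease CTSL (1.33) and the galactosidase GLA (1.32). There was 1 p53 target that fell adjusted over the list alone, and the other counts were the same.

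Matrix, contractile and interferon-induced genes were lower at day 7 than in growing cells. Of 24 extracellular matrix genes 17 fell and 2 rose (median -0.57, adjusted p = 1.96e-07, and adjusted p = 0.0782 with an estimated correlation), with the proteoglycan DCN at -2.54, FBLN1 at -2.26 and the collagen COL3A1 at -1.71. Of 19 contractile and SRF genes 16 fell and none rose (median -0.61, adjusted p = 5.56e-09, and adjusted p = 0.0891 with an estimated correlation), with the actin regulators LMOD1 at -2.79 and TAGLN at -1.97. Of 28 interferon-induced genes 17 fell and none rose (median -0.39, adjusted p = 4.56e-05), with IFIT2 at -2.27 and IFIT1 at -2.25, and this call held with an estimated correlation (adjusted p = 0.0457). Adjusted over the list alone, 1 contractile and 1 interferon-induced gene rose, and the other counts were the same.

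The other 10 lists did not pass at day 7 against growing cells. Of 16 senescence regulators and markers 7 rose and 4 fell (list adjusted p = 0.314), and of 14 immediate early genes 6 rose and 2 fell (0.12). Of 19 FOXO targets 4 rose and 10 fell (0.0695), of 18 cholesterol synthesis genes 7 rose and 4 fell (0.127), and of 21 genes of the unfolded protein and stress response 6 rose and 10 fell (0.362). Of 24 oxidative phosphorylation genes 9 rose and 3 fell (0.328), and of 23 H3K4 methylation enzymes 9 rose and 3 fell (0.328), with KDM5C, a related demethylase, at 0.69. Markers of other cell types, measured beside these groups, did not pass either. Of 14 epithelial markers 5 fell and none rose (0.12), of 12 endothelial markers 5 rose and none fell (0.0769), and of 12 immune cell markers 2 rose and 1 fell (0.375). In these lists, adjusted over the list alone, 5 senescence regulators and 11 FOXO targets fell, 10 cholesterol and 10 oxidative phosphorylation genes and 4 endothelial markers rose, and the other counts were the same. Without the 4 arrays of narrow range, FOXO targets (median -0.28, adjusted p = 0.0323, and adjusted p = 0.255 with an estimated correlation) and cholesterol synthesis genes (median 0.31, adjusted p = 0.0259, and adjusted p = 0.47 with an estimated correlation) passed.

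In all, 8049 of 17866 genes passed the test between day 7 and growing cells, 4134 higher and 3915 lower, and 1118 of them changed at least 2-fold (457 higher, 661 lower). Of the called genes 51.4% were higher, and 62.0% with each array centred on its median gene. Centring shifted every gene by 0.07 in this comparison and by at most 0.09 in any other, and changed the sign of no list that passed. With shLuc alone, in a fit that assumed the single arrays to vary like the duplicates, 3320 genes passed.

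Senescent day 3 was compared with growing cells to see which changes were present earlier. IL1B was already raised by 6.53 (SE 0.17), MMP3 by 6.29, IL1A by 5.02, CXCL8 by 5.07, TNFSF15 by 5.18 and GABRA2 by 5.37. TAGLN3, a relative of the contractile gene TAGLN, rose by 5.08 and DCSTAMP, which functions in cell fusion, by 4.99. Falls were seen for PLPPR4 (-4.37), CHRM2 (-4.26), KIT (-4.14), SLC7A14 (-4.07), the glycosyltransferase GCNT4 (-3.73), CEMIP (-3.37), the antisense RNA PKD1L1-AS1 (-3.36) and the claudin CLDN11 (-3.32). These 16 changes had adjusted p from 2.25e-15 to 5.03e-10, with the same sign in 4 of 4 lines, as the naming rule required. HRAS rose by 2.02, CDKN2B by 2.13, CDKN1A by 0.45 and CDKN2A by 0.34, and LMNB1 fell by 1.98. KDM5B did not pass (0.14, adjusted p = 0.238), but did without the shJarid1b line (0.25, adjusted p = 0.0152). KDM5A (-0.08, adjusted p = 0.564) did not pass.

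At day 3 against growing cells 12 lists passed. All 34 mitosis genes fell (median -1.866, adjusted p = 2.12e-22, and adjusted p = 0.111 with an estimated correlation). Of the DNA replication genes 28 of 38 fell (adjusted p = 0.143 with an estimated correlation), and of the G1/S and E2F target genes 20 of 30 (adjusted p = 0.166 with an estimated correlation). Of the secretory genes 21 of 28 rose (median 1.60, adjusted p = 3.56e-09, and adjusted p = 0.102 with an estimated correlation). RAS and MAPK output rose in 18 of 22 genes, including the feedback inhibitor SPRY4 (1.52), and matrix genes fell in 19 of 24, and both calls held with an estimated correlation (adjusted p = 0.0497 for each). Of 14 immediate early genes 11 rose (median 0.60, adjusted p = 7.35e-04, and adjusted p = 0.143 with an estimated correlation), among them the transcription factors EGR3 (1.17) and MYC (0.93). Cholesterol synthesis genes fell in 10 of 18 (median -0.30, adjusted p = 0.00269, and adjusted p = 0.491 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at -0.88. The remaining calls were ribosome biogenesis (17 of 20 rose, adjusted p = 0.0844 with an estimated correlation), contractile and SRF genes (16 of 19 fell, 0.0844), interferon-induced genes (15 of 28 fell, 0.0802) and p53 targets (14 of 22 rose, 0.161). Adjusted over the list alone, 29 DNA replication, 20 matrix and 17 contractile genes fell and 22 secretory genes rose, with the other majority counts of these 12 lists the same. FOXO targets passed as well without the narrow arrays (median -0.21, adjusted p = 0.042, and adjusted p = 0.345 with an estimated correlation).

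In all, 8182 genes passed between day 3 and growing cells, 4406 higher and 3776 lower (53.9% higher, and 60.6% with each array centred), and 2332 with shLuc alone. The changes at day 3 and day 7 overlapped: 3314 genes were higher and 3133 lower at both times, against 1020 and 827 for independent lists, and 57 had opposite signs. In simulated data with the shared growing arrays and no effect, the same numbers of genes, taken by smallest p, shared 1895 higher and 1918 lower. Across genes, which are not independent replicates, the 2 sets of changes had r = 0.928 (covariance 0.275, against 0.00395 simulated), and r was 0.892 on average when each time was compared with different growing arrays.

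Day 7 was then compared with day 3 of senescence directly. The protease inhibitor SERPINB4 rose by 2.68 (SE 0.19), the interferon-inducible chemokine CXCL10 by 2.42, the complement component C3 by 2.33, the receptor MRGPRX3 by 2.27, the epithelial transcription factor EHF by 2.20, the cornified envelope gene LCE3D by 1.98, the protease CTSS by 1.866 and CRCT1 by 1.83. The microRNA gene MIR222 fell by 3.01 (SE 0.17), as did the linker histone gene H1-4 (-1.68), the TNF receptor family member TNFRSF9 (-1.48), DLGAP5 (-1.47) and CDK1 (-1.42). The clock genes CIART (-2.17), NR1D1 (-1.73) and PER3 (-1.51) were also lower. These 16 changes had adjusted p from 3.93e-08 to 1.56e-04 and the same sign in 4 of 4 lines, as the naming rule required. Whether the probe sets of MIR222 and H1-4 measured these RNAs or other transcripts of their loci was not tested. CDKN1A rose by 0.39 and CDKN2B by 0.47, whereas HRAS (-0.11, adjusted p = 0.192), LMNB1 (-0.17, adjusted p = 0.32) and CDKN2A (0.11, adjusted p = 0.346) did not pass.

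From day 3 to day 7, 12 lists passed and none held with an estimated correlation. Cholesterol synthesis genes rose in 16 of 18 (median 0.51, adjusted p = 1.86e-16, and adjusted p = 0.136 with an estimated correlation), with HMGCS1 at 1.03 and DHCR7, a late enzyme, at 0.77. The size of this rise differed between the duplicates. With the first day 7 arrays the list mean stood 0.63 above day 3 (0.44 to 0.71 over the 4 lines), and with the second arrays 0.32 (-0.0014 to 0.44, lowest with shJarid1a), lower than the first in 4 of 4 lines. Mitosis genes fell in 27 of 34 (median -0.65, adjusted p = 3.61e-17, and adjusted p = 0.184 with an estimated correlation). Secretory genes rose in 12 of 28 (median 0.37, adjusted p = 1.84e-08, and adjusted p = 0.136 with an estimated correlation), with the chemokine CXCL5 at 1.62, the metalloproteinase MMP10 at 1.52 and IL1A at 1.40. Matrix genes rose in 11 of 24 (median 0.20), ribosome biogenesis genes fell in 13 of 20 (median -0.23) and immediate early genes fell in 7 of 14 (median -0.25), each with adjusted p = 0.136 with an estimated correlation. The other 6 calls were DNA replication (14 of 38 fell, adjusted p = 0.307 with an estimated correlation), G1/S (13 of 30 fell, 0.274), interferon-induced (6 of 28 fell, 0.184), p53 (9 of 22 rose and 3 fell, 0.274), lysosome (3 of 22 rose, 0.284) and unfolded protein response genes (6 of 21 rose, 0.274). With the first and the second day 7 arrays, list means were 0.16 and 0.26 for matrix, 0.11 and 0.06 for p53, 0.10 and 0.05 for lysosome and -0.16 and -0.11 for interferon-induced genes. Adjusted over the list alone, 17 cholesterol, 16 secretory and 13 matrix genes rose, and 32 mitosis, 16 DNA replication, 14 G1/S, 16 ribosome biogenesis, 9 immediate early and 7 interferon-induced genes fell. In all, 3106 genes passed, 1470 higher and 1636 lower. The share higher was 47.3%, and 59.8% with each array centred. The count was 1668 without the shLuc line, 1847 without the shtandem line and 101 with shLuc alone.

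Quiescent cells were compared with growing cells as a reversible arrest. SLITRK6, a membrane protein of neurons, rose by 3.94 (SE 0.25), the sodium channel gene SCN7A by 3.93, the growth factor PDGFD by 3.39, the alcohol dehydrogenase ADH1B by 3.13, SIPA1L2 by 3.06, the semaphorin receptor PLXNC1 by 2.93, ARHGAP28 by 2.90 and CXCL10 by 2.87. The mitotic kinase gene PBK fell by 3.08 (SE 0.17), as did the G protein regulator RGS4 (-3.04), the hyaluronan synthase HAS2 (-3.01), DLGAP5 (-2.97), CDC20 (-2.83) and CDK1 (-2.79). ID3 (-2.83) and ID1 (-2.79), inhibitors of differentiation, fell too. These 16 changes had adjusted p from 7.68e-11 to 6.14e-08 and the same sign in 4 of 4 lines, as the naming rule required. CDKN2B rose by 1.09, CDKN1A by 0.25 and CDKN2A by 0.25, while LMNB1 (-1.45), CCND1 (-0.28) and HRAS (-0.26) fell. KDM5B rose by 0.37 (adjusted p = 0.00657) and KDM5A by 0.32 (adjusted p = 0.0358). The KDM5B call was lost without the shtandem line (0.34, adjusted p = 0.0585). That of KDM5A was lost without the shLuc (0.34, adjusted p = 0.0986), shJarid1b (0.30, adjusted p = 0.0799) or shtandem line (0.28, adjusted p = 0.189), and with centred arrays (0.30, adjusted p = 0.0521).

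In quiescence 12 lists passed. All 34 mitosis genes (median -2.16, adjusted p = 8.9e-35), 32 of 38 DNA replication genes (median -0.72) and 28 of 30 G1/S and E2F target genes (median -0.76) fell, each with adjusted p = 0.06 with an estimated correlation. FOXO targets rose in 15 of 19 (median 0.57, adjusted p = 6.79e-10), including SESN3 and KLHL24 (1.26 each) and TXNIP (1.10), and this call held with an estimated correlation (adjusted p = 0.0209). Matrix genes rose in 16 of 24 (median 0.38, adjusted p = 5.37e-07, and adjusted p = 0.06 with an estimated correlation), with the matricellular gene POSTN at 2.11, the proteoglycan LUM at 1.22 and FBLN1 at 1.12. Ribosome biogenesis genes fell in 19 of 20 (median -0.40, adjusted p = 8.46e-12, and adjusted p = 0.06 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 18 (adjusted p = 0.315 with an estimated correlation), p53 targets in 12 of 22 (0.075), unfolded protein and stress response genes in 13 of 21 (0.337) and lysosome genes in 10 of 22 (0.364), while RAS and MAPK output fell in 11 of 22 (0.2) and oxidative phosphorylation in 7 of 24 (0.364). In quiescence 14 cholesterol, 13 p53, 14 unfolded protein response and 12 lysosome genes rose adjusted over the list alone, and 33 DNA replication and 20 ribosome biogenesis genes fell. In all, 5716 genes passed, 2943 higher and 2773 lower, and 732 with shLuc alone. The share higher was 51.5%, but 45.6% with each array centred, so the majority turned with the scaling.

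Senescent day 7 was compared with quiescent cells to set the 2 kinds of arrest side by side. IL1B rose by 7.49 (SE 0.17), MMP3 by 7.12, IL1A by 6.46, the interleukin receptor IL13RA2 by 5.80, EHF by 5.56, the cornified envelope gene LCE2C by 5.51, GABRA2 by 5.44 and TNFSF15 by 5.36. Lower in senescence were SLC7A14 (-5.90), CEMIP (-5.16), PDGFD (-5.10), the serotonin receptor HTR2B (-5.07), SCN7A (-4.79), CHRM2 (-4.75), PLPPR4 (-4.64) and the iron exporter SLC40A1 (-4.64). These 16 changes had adjusted p from 7.94e-16 to 1.72e-11 and the same sign in 4 of 4 lines, as the naming rule required. CDKN2B was higher in senescence by 1.51 and CDKN1A by 0.59, and KDM5A was lower by 0.40 (log2 change -0.40, adjusted p = 0.00576). With shLuc alone the change of KDM5A was -0.20. The mean over the lines includes those whose hairpin targets KDM5A, in which the fall was larger. The log2 level in quiescence and on the day 7 arrays was 8.055 against 7.411 and 7.187 with shJarid1a. It was 8.57 against 8.127 and 8.132 with shtandem, 9.519 against 9.346 and 9.288 with shLuc, and 9.459 against 9.189 and 9.331 with shJarid1b. KDM5B (-0.21, adjusted p = 0.0753) did not pass, but did without the shLuc line (-0.29, adjusted p = 0.0374). In shLuc the KDM5B level was 10.58 in quiescence and 10.57 and 10.67 at day 7.

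Between day 7 senescence and quiescence 9 lists passed, and 4 held with an estimated correlation. RAS and MAPK output rose in 19 of 22 genes (median 0.98, adjusted p = 9.13e-09, and adjusted p = 0.0244 with an estimated correlation), while matrix genes fell in 21 of 24 (median -0.79, 0.0368 with an estimated correlation), FOXO targets in 14 of 19 (median -0.90, 0.0368) and interferon-induced genes in 17 of 28 (median -0.57, 0.0351). Secretory genes rose in 21 of 28 (median 2.27, adjusted p = 7.96e-08, and adjusted p = 0.119 with an estimated correlation), and ribosome biogenesis in 18 of 20 (median 0.78, adjusted p = 0.0698 with an estimated correlation). Contractile and SRF genes fell in 16 of 19 (median -0.80, adjusted p = 0.11 with an estimated correlation), mitosis genes fell in 20 of 34 and rose in 4 (median -0.42, adjusted p = 0.695 with an estimated correlation), and unfolded protein response genes fell in 11 of 21 (adjusted p = 0.53 with an estimated correlation). DNA replication genes (11 rose, 15 fell, list adjusted p = 0.488) and G1/S and E2F target genes (11 rose, 12 fell, 0.638) did not pass, and oxidative phosphorylation genes passed only without the narrow arrays (median 0.20, adjusted p = 0.0436, and adjusted p = 0.379 with an estimated correlation). Adjusted over the list alone, 19 ribosome biogenesis genes rose, and 17 contractile, 21 mitosis and 16 DNA replication genes fell, with the other majority counts the same. In all, 9269 genes passed, 4778 higher and 4491 lower. The share higher was 51.5%, and 65.0% with each array centred, and 4854 genes passed with shLuc alone.

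The changes from growing cells in senescence at day 7 and in quiescence shared 818 higher and 909 lower genes, against 681 and 608 for independent lists, while 2231 genes moved in opposite directions. The simulated data, with as many genes taken by smallest p, gave 1468 higher and 1460 lower in both and 327 opposite. Those genes held only noise from the shared arrays, so their overlap is no reference for genes with real effects. No value for independent lists was computed for the opposite genes. Across genes r was 0.0933 (covariance 0.0187, against 0.00398 in simulated data with shared growing arrays and no effect). With different growing arrays for the 2 comparisons, r averaged 0.0747, from 0.0308 to 0.125.

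**Figure D2:**
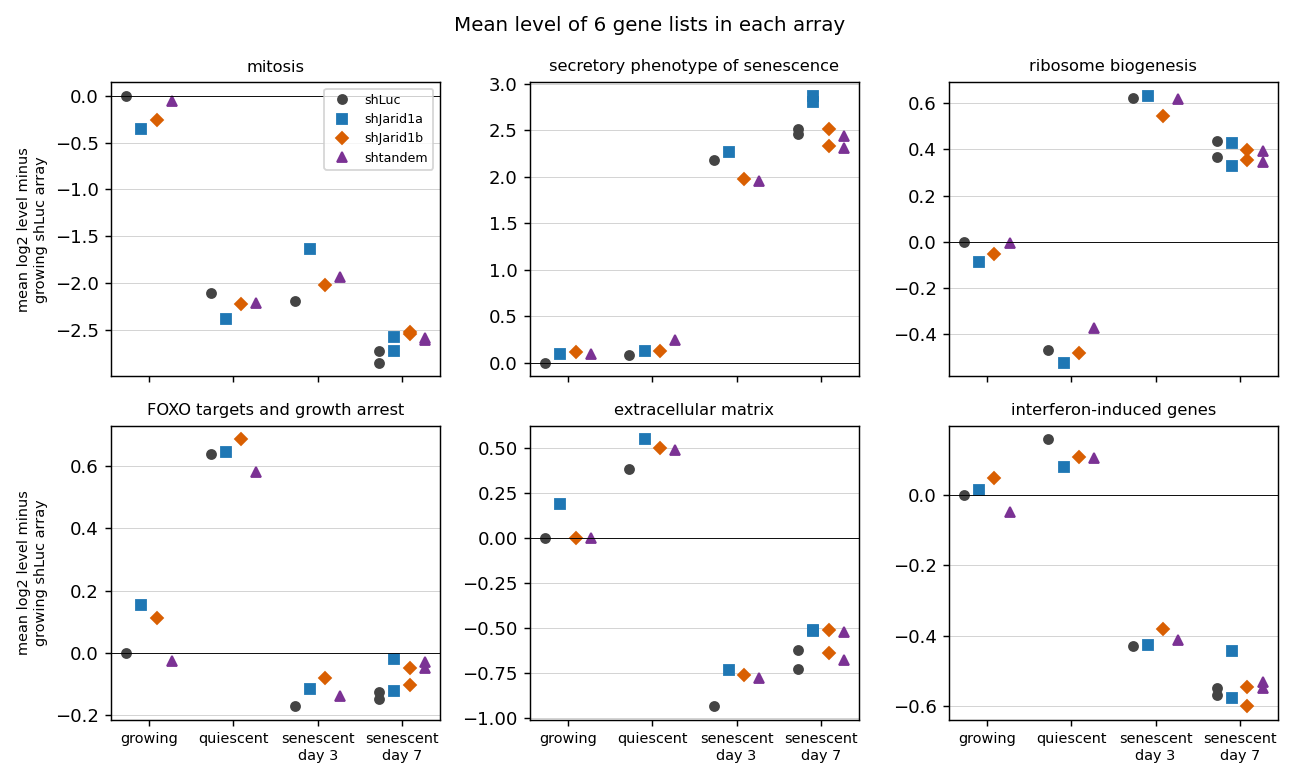
Mean level of 6 gene lists on each array minus that on the growing shLuc array (vertical axis, log2 units) by state (horizontal axis), with 1 point per array and the hairpin shown by colour. Mitosis genes fell in quiescent cells and at both senescent times, secretory genes rose in senescence, and ribosome biogenesis and matrix genes changed in opposite directions in quiescence and senescence.

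The hairpins were next compared with shLuc at day 7, the state with duplicates, to see which genes differed in senescent cells. The targets were lowered only in part, as given above. The labels name a single hairpin against each gene, besides shtandem. Effects of lower KDM5A or KDM5B therefore cannot be told apart from effects of a hairpin on other RNAs. Only KDM5A passed with shJarid1a (-2.02, SE 0.12, adjusted p = 3.56e-04). With shJarid1b, KDM5B fell by 2.09 (SE 0.13, adjusted p = 6.4e-04), and the lipid carrier gene FABP4 rose by 1.70 (SE 0.15, adjusted p = 0.00964), the thrombin receptor family gene F2RL2 by 1.30 (adjusted p = 0.0448) and the neural adhesion gene NCAM2 by 0.98 (adjusted p = 0.0308). With shtandem, FABP4 rose by 1.872 (SE 0.15, adjusted p = 0.00411), F2RL2 by 1.76 (adjusted p = 0.00429), NCAM2 by 1.32 (adjusted p = 0.00411) and the desmosomal cadherin gene DSG2 by 1.01 (adjusted p = 0.0343), while KDM5A (-1.19, adjusted p = 0.0102) and KDM5B (-1.08, adjusted p = 0.0355) fell. Each had the same sign in 4 of 4 pairs of arrays, which the rule for the largest changes required, and these pairs share arrays. CCNA2 was at 0.20 with shJarid1a (adjusted p = 1), 0.23 with shJarid1b (adjusted p = 0.671) and 0.38 with shtandem (adjusted p = 0.627), and CDKN1A, CDKN2A, CDKN2B, RB1, LMNB1, HRAS, PCNA and CCND1 did not pass with any hairpin.

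The number of genes past the threshold at day 7, 1 with shJarid1a, 4 with shJarid1b and 6 with shtandem, depended on single arrays. A hairpin left with 1 array was assumed to vary like the duplicates of the other 3, with 3 residual degrees of freedom, so a lost call there is not a weaker effect. The shtandem count by limma was 0 without either shtandem array (712 genes at an unadjusted p under 0.05 without the first and 889 without the second), 3 without the second shLuc array, and 14 without either shJarid1a array. The shJarid1b count was 1 without the second shLuc array, the second shJarid1b array or either shtandem array, 2 without the first shJarid1b array, and 8 without the first shLuc array. The shJarid1a count was 4 without the first shLuc array. Each of FABP4, F2RL2, NCAM2, DSG2 and the targets of shtandem lost its call in some of these fits, with FABP4 at 1.51 to 1.92, F2RL2 at 1.27 to 1.88, NCAM2 at 0.95 to 1.33, DSG2 at 0.93 to 1.09, KDM5A with shtandem at -1.22 to -1.16 and KDM5B with shtandem at -1.19 to -0.98 where the call was lost. At an unadjusted p under 0.05 there were 830, 1491 and 1420 genes. With limma-trend the counts were 4, 15 and 31. More genes also passed with each hairpin when the replicate number was entered as a block, with counts given under processing. Whether the numbers pair the arrays is not known, and they were not taken to do so.

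Gene lists at day 7 shifted with the hairpins by small amounts, and no list call held with an estimated correlation. All 3 hairpins were compared with the same 2 shLuc arrays, so a feature of those arrays would appear in each comparison. Relative to growing shLuc, mitosis means were -2.72 and -2.851 with shLuc and -2.576 and -2.729 with shJarid1a, which overlap. They were -2.519 and -2.544 with shJarid1b and -2.61 and -2.583 with shtandem, which do not overlap with shLuc. Mitosis genes were higher in 27 of 34 with shJarid1a (median 0.16, adjusted p = 3.86e-04, and adjusted p = 0.457 with an estimated correlation), in 29 with shJarid1b (median 0.17, adjusted p = 2.74e-08, and adjusted p = 0.338 with an estimated correlation) and in 28 with shtandem (median 0.19, adjusted p = 4.09e-05, and adjusted p = 0.732 with an estimated correlation). DNA replication genes were higher in 26, 27 and 27 of 38 (adjusted p = 0.505, 0.773 and 0.837 with an estimated correlation). G1/S genes were higher in 23 of 30 with shJarid1a (adjusted p = 0.505 with an estimated correlation) and 22 with shJarid1b (0.773), and contractile genes in 12, 15 and 12 of 19 with the 3 hairpins (adjusted p = 0.582, 0.773 and 0.837 with an estimated correlation). With shJarid1a, secretory genes were higher in 23 of 28 (median 0.31, adjusted p = 1.4e-09, and adjusted p = 0.457 with an estimated correlation), whereas their median was -0.10 with shJarid1b (12 higher, adjusted p = 0.532) and -0.07 with shtandem (10 higher, adjusted p = 0.112). Also with shJarid1a, cholesterol synthesis genes were lower in 17 of 18 (median -0.25, adjusted p = 1.65e-06, and adjusted p = 0.505 with an estimated correlation). The p53 targets were lower in 19 of 22 (median -0.14, adjusted p = 0.457 with an estimated correlation), lysosome genes in 17 of 22 (adjusted p = 0.505 with an estimated correlation) and H3K4 enzymes in 15 of 23 (adjusted p = 0.457 with an estimated correlation), a list that holds KDM5A and KDM5B and did not pass without them (adjusted p = 0.0767), while matrix genes were higher in 18 of 24 (adjusted p = 0.505 with an estimated correlation). Epithelial markers were lower in 13 of 14 with shJarid1b (adjusted p = 0.00345, and adjusted p = 0.773 with an estimated correlation). Without the 4 arrays of narrow range the epithelial and DNA replication calls with shJarid1b were lost. Lists that passed only then were lower cholesterol synthesis (median -0.19) and higher matrix genes (0.07) with shJarid1b, lower secretory (-0.18), p53 (-0.08) and cholesterol synthesis genes (-0.15) with shtandem, and lower senescence regulators (-0.10) with shJarid1a, with adjusted p from 0.633 to 0.727 with an estimated correlation. Apart from KDM5A and KDM5B no member of these lists passed over all genes. When adjusted over the list alone, 9 secretory, 3 DNA replication, 4 contractile and 1 matrix gene rose with shJarid1a, 4 mitosis, 1 G1/S and 3 contractile genes with shJarid1b, and 7 DNA replication and 2 contractile genes with shtandem.

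Over the 4 states, with each state weighing the same, the hairpins changed 18 genes (shJarid1a, 14 higher), 10 (shJarid1b, 9 higher) and 38 (shtandem, 35 higher). With shJarid1a, POSTN rose by 0.94 (SE 0.14, adjusted p = 0.0251), TNFAIP6, a hyaluronan-binding protein induced by inflammation, by 0.86 (adjusted p = 0.0148), RFTN2 by 0.81, PCDHB15, a protocadherin, by 0.55, TRO by 0.54, the mannosidase MAN2A1 by 0.53 (adjusted p = 6.05e-04), MINDY3 by 0.52 and NEDD9 by 0.49. The neuronal pentraxin NPTX1 (-0.59), the nucleoporin SEH1L (-0.48) and the adhesion receptor ADGRG1 (-0.44) fell. With shJarid1b, CCND2, a cyclin of G1 phase, rose by 0.84 (SE 0.11, adjusted p = 0.0109), ANKRD1, a muscle ankyrin repeat protein, by 0.73 (adjusted p = 0.0143), TMEM170A by 0.58, TMEM254 by 0.48, CASS4 by 0.47, MAN2A1 by 0.44, SPOCK1 by 0.43 and the copper transporter SLC31A2 by 0.39. With shtandem, ANKRD1 rose by 1.14 (SE 0.10, adjusted p = 2.23e-04), SPP1, the osteopontin gene, by 1.12 (adjusted p = 0.0102), the NADPH oxidase NOX4 by 0.84, NCAM2 by 0.81, CCND2 by 0.81, TNFAIP6 by 0.76, the endothelin gene EDN1 by 0.74, CALB2 by 0.66 and the activin subunit INHBA by 0.64, while ASB2 fell by 0.44 (adjusted p = 0.0471). Each named gene had the same sign in 4 of 4 states, which the rule for the largest changes required. Besides these, KDM5A and KDM5B fell with the hairpins against them.

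The hairpin lines shared some of these genes. FAM107B, MAN2A1 and TMEM170A rose with all 3 hairpins. With both single hairpins 4 genes were higher, against 0.00705 for independent lists. With shtandem, shJarid1a shared 9 higher and 1 lower gene (KDM5A), and shJarid1b shared 6 higher and 1 lower gene (KDM5B). In simulated data with shared shLuc arrays and no effect, as many genes taken by smallest p shared 0.75, 1.5 and 1.15 higher genes on average in these 3 pairs, so part of the overlap may come from the shared arrays. Across genes r was 0.578 between the single hairpins, 0.633 between shJarid1a and shtandem and 0.649 between shJarid1b and shtandem, against 0.488, 0.491 and 0.504 in the simulated data. The covariances were 0.00643, 0.00714 and 0.00703 against 0.00384, 0.00387 and 0.00397. With different shLuc arrays for each hairpin, r averaged 0.233, 0.207 and 0.168.

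Over the states, list shifts were small, and of the 9, 4 and 4 lists that passed with shJarid1a, shJarid1b and shtandem none held with an estimated correlation. Matrix genes were higher in 22 of 24 with shJarid1a (median 0.13, adjusted p = 2.05e-08, and adjusted p = 0.166 with an estimated correlation) and in 19 with shJarid1b (median 0.07, 0.72 with an estimated correlation). Contractile and SRF genes were higher in 13 of 19 with shJarid1a (median 0.08, adjusted p = 0.463 with an estimated correlation), in 16 with shJarid1b (median 0.09, 0.72) and in 17 with shtandem (median 0.09, adjusted p = 5.66e-06, and adjusted p = 0.891 with an estimated correlation). Cholesterol synthesis genes were lower in 16 of 18 with shJarid1a (median -0.13, adjusted p = 2.3e-05, and adjusted p = 0.463 with an estimated correlation), in 15 with shJarid1b (0.793) and in 15 with shtandem (0.916), where the call was lost with the mean of all probe sets. The other calls were higher secretory (23 of 28), FOXO (12 of 19) and unfolded protein response genes (16 of 21) and lower p53 (15 of 22), immediate early (12 of 14) and ribosome biogenesis genes (14 of 20) with shJarid1a, lower ribosome biogenesis genes (15 of 20) with shJarid1b, and higher oxidative phosphorylation genes (21 of 24) and lower H3K4 enzymes (13 of 23) with shtandem, the last lost without KDM5A and KDM5B (adjusted p = 0.628). Their adjusted p with an estimated correlation ran from 0.463 to 0.916. Without the narrow arrays the p53, immediate early, FOXO, unfolded protein response and ribosome biogenesis calls with shJarid1a were lost. So were the matrix and ribosome biogenesis calls with shJarid1b and the oxidative phosphorylation call with shtandem. Lower mitosis genes with each of the hairpins, and lower G1/S genes with shJarid1a, passed only without those arrays. That fit held no day 3 shLuc array, so day 3 gave no direct comparison with shLuc. The mitosis medians with shJarid1a, shJarid1b and shtandem were 0.58, 0.16 and 0.27 at day 3, and -0.38, -0.26 and -0.08 in growing cells. The lower sign therefore cannot be set apart from the loss of that state. At day 7 the mitosis genes were instead higher with each hairpin. By p adjusted over the list alone, 6 matrix genes rose with shJarid1a and 3 contractile genes with shtandem, while over all genes 1 did in each list, POSTN and ANKRD1. Without the growing, quiescent, day 3 or day 7 arrays in turn, the counts of called genes were 2, 5, 5 and 4 with shJarid1a, 1 each time with shJarid1b (KDM5B), and 7, 4, 10 and 8 with shtandem. Of 34 calls of named genes over the states, 7, 10, 13 and 12 were kept in these fits. Without the 4 arrays of narrow range, a choice added after the data were examined, they were 4, 4 and 12.

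The shtandem hairpin was compared with the mean of the single hairpins over the states. This does not isolate what targeting both genes adds, since each single hairpin lowered only its own target and the levels differed. KDM5A stood at 46.5% of shLuc with shtandem and 30.6% with shJarid1a. KDM5B stood at 48.1% with shtandem and 27.8% with shJarid1b. ANKRD1 was higher by 0.69 with shtandem (SE 0.09, adjusted p = 0.0349, 4 of 4 states) and was the only gene past the threshold. Against shLuc, ANKRD1 differed by 1.14 with shtandem, 0.73 with shJarid1b and 0.17 with shJarid1a. At an unadjusted p under 0.05 there were 779 genes, and 2 passed with limma-trend. No gene passed by limma without any of the 4 states (615 to 782 genes at an unadjusted p under 0.05) or without the narrow arrays (1006 genes). Among 9 lists that passed with the preset correlation, ribosome biogenesis genes were higher in 18 of 20 (median 0.04, adjusted p = 8.2e-04, and adjusted p = 0.487 with an estimated correlation) and matrix genes lower in 20 of 24 (median -0.03, adjusted p = 0.00341, and adjusted p = 0.487 with an estimated correlation). No gene of either list passed when adjusted over the list alone. Without the narrow arrays only the secretory and matrix calls held among the 9, and the ribosome biogenesis call was lost.

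Whether the shtandem effect differed between senescence and the other states was tested as an interaction. No gene passed by limma for day 7 against growing cells (smallest adjusted p = 1, 490 genes at an unadjusted p under 0.05, 0 by limma-trend), and none for day 7 against quiescent cells (smallest adjusted p = 0.208, 652 genes, 2 by limma-trend). Without either day 7 shJarid1a array, 1 gene, SSTR5-AS1, passed in the first of these (-2.50, adjusted p = 0.0442). The smallest p against growing cells belonged to ENPP4 (1.12), FABP4 (1.55) and F2RL2 (1.40) among higher values, and to SSTR5-AS1, the mucosal gene C6orf15 (-1.73) and the thrombomodulin gene THBD (-1.07) among lower ones. Against quiescent cells they belonged to FABP4 (2.23, adjusted p = 0.208), F2RL2 (1.75, adjusted p = 0.473), DSG2 (1.05), CD200 (-1.36, adjusted p = 0.37), IL1B (-1.21, adjusted p = 0.82) and SERPINA3 (-1.01), of which FABP4 and F2RL2 passed with limma-trend (adjusted p = 0.0289 each). In simulated data this test found 17.9% of genes changed by 1 log2 unit and 69.7% of those changed by 2, against 70.2 and 95.5% for the day 7 comparison, and 100% for both sizes over the states.

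The interaction moved the cell cycle lists toward higher values at day 7. DNA replication genes were higher in 34 of 38 relative to growing cells (median 0.28, adjusted p = 2.09e-07, and adjusted p = 0.638 with an estimated correlation) and mitosis genes in 29 of 34 (median 0.26, adjusted p = 7.12e-06, and adjusted p = 0.638 with an estimated correlation). Relative to quiescent cells, mitosis genes were higher in 29 of 34 (median 0.35, adjusted p = 4.27e-07, and adjusted p = 0.437 with an estimated correlation) and secretory genes lower in 19 of 28 (median -0.30, adjusted p = 0.00248, and adjusted p = 0.655 with an estimated correlation). In the interaction, adjusted over the list alone, 1 secretory gene was lower and no cell cycle gene passed. The median of 102 cell cycle genes relative to shLuc with shtandem was -0.07 in growing cells, -0.04 in quiescent cells, 0.16 at day 3 and 0.12 at day 7. With shJarid1a it was -0.28, -0.15, 0.31 and 0.12, and with shJarid1b -0.17, -0.05, 0.10 and 0.14. The values in growing cells rest on 1 shLuc array, whose cell cycle genes stood 0.181 above the other growing arrays, the highest such deviation within a state among the 20 arrays. The comparison with quiescent cells does not use that array.

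**Figure D3:**
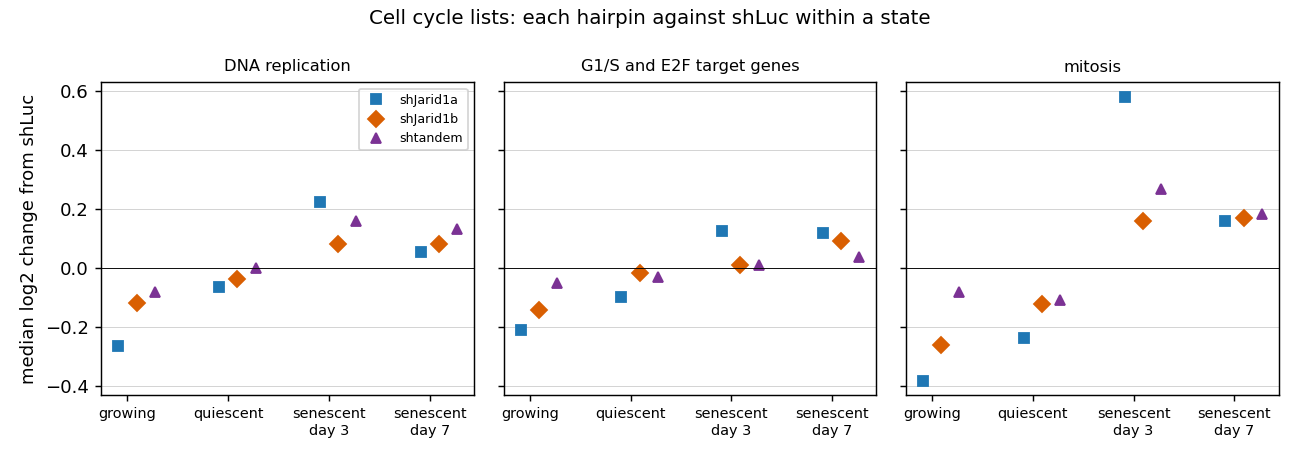
Median log2 change from shLuc (vertical axis) of the DNA replication, G1/S and mitosis lists for each hairpin, by state (horizontal axis). The DNA replication median with shtandem was -0.08 in growing cells, and the mitosis median at day 7 was 0.19 with shtandem.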

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

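The tests of small RNA genes and of dividing cells in the narrow arrays were chosen only after the result was seen. So were those of lower demethylase RNA and of the response in each hairpin line, and the 4 narrow arrays themselves. The interaction results below stood out because the shtandem effect differed between states for 10 list tests with the preset correlation, although none passed with an estimated correlation.

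The shtandem effect on the cell cycle lists was more positive at day 7 than in growing cells: the median difference was 0.2829 for DNA replication, 0.1796 for G1/S and E2F target genes and 0.2573 for mitosis genes, and 0.230 over the 102 genes together. The second day 7 shLuc array, which had a narrow range, was argued against as the whole cause, since without it the difference was 0.178 (0.156 and 0.228 with each of the 2 day 7 shtandem arrays). A weaker senescence response of all genes in the shtandem cells may account for part of it. The response of 1083 genes outside these lists was smaller by 8.27% (7.22 to 9.39%) and that of the cell cycle genes by 9.53% (7.24 to 11.9%). Both shares give most weight to genes with a large response, and their intervals over genes hold no spread between arrays. Without the second day 7 shLuc array the shares were 9.48% and 7.24%, in the other order. Relative to the growing shLuc array, the DNA replication mean with shtandem was -0.0823 in growing cells and -0.979 and -0.934 at day 7. With shLuc it was -1.087 and -1.172 at day 7. The response of this list was thus smaller by more than 8.27%, a loss that an equal weakening of all genes does not cover. Lower RNA of the 2 demethylases in senescent cells stays open and undecided. The shtandem effect was higher at day 3 than in quiescent cells by 0.224, but this is a difference of 4 single arrays, of which the day 3 shLuc array had a narrow range too. By the day 7 duplicates such a difference has 2 SD of 0.210 and a 95% limit of 0.292 (t, 4 degrees of freedom). The value lies beyond 2 SD and within the limit by t, which was used because the SD rests on 4 differences. After the value was seen, this limit replaced 2 SD and, before that, a range from random gene lists (-0.0766 to 0.0368), which held no spread between arrays, and by either of those the explanation would have been favoured. In the lines with a single hairpin the cell cycle response was smaller by 38.7% at day 3 and 17.7% at day 7 (shJarid1a), and by 16.9 and 16.7% (shJarid1b), against 5.29, 1.62, 6.66 and 6.33% for other genes. With shtandem at day 3 it was smaller by 13.4%, against 9.07% for other genes, and no test separated the 2 open explanations. All of these responses share the growing shLuc array, whose cell cycle genes stood 0.181 above the other growing arrays, and its part in the difference from growing cells was not tested.

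Against quiescent cells, the shtandem effect at day 7 was higher by a median of 0.216 in 38 DNA replication genes, 0.0847 in 30 G1/S and E2F target genes and 0.3471 in 34 mitosis genes. The secretory list differed by -0.1444 against growing cells (12 of 28 genes higher, adjusted p = 0.83 with an estimated correlation) and by -0.295 against quiescent cells (9 of 28 higher, adjusted p = 0.655 with an estimated correlation). Contractile and SRF genes differed by 0.1478 against growing cells (13 of 19 higher, adjusted p = 0.83 with an estimated correlation). Oxidative phosphorylation genes differed by 0.07372 against growing cells (16 of 24 higher, adjusted p = 0.83 with an estimated correlation). Without the narrow arrays the contractile and oxidative phosphorylation calls were lost. Matrix genes then passed against growing cells, and p53 targets and ribosome biogenesis genes against quiescent cells.

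The 4 arrays with a narrow spread of values (interquartile range 3.73 to 3.796) all came from senescent cells, with 2 of them shLuc arrays. A mislabelled growing or quiescent sample was argued against, since the lowest HRAS value among them was 10.82, above the 8.602 to 8.996 of growing and quiescent arrays. A different share of dividing cells stays open: the cell cycle genes deviated downward in all 4, beyond the -0.180 to 0.181 of the other 16 arrays only in the day 3 shLuc array (-0.239), and by -0.0913 in the array nearest 0 (bootstrap interval -0.160 to -0.0204). RNA preparation or labelling of these samples may differ and stays open too: small nucleolar and Cajal body RNA genes deviated downward in all 4, beyond the range of the other arrays in 3, and by -0.1189 in the fourth (-0.164 to -0.0714), within -0.128 to 0.114. The rule first written, that 1 array inside that range excludes the explanation, would have excluded both. It was changed for both after the values were seen, since a shift of 1 direction within the range of other states is not forbidden by either, and arrays deviating in opposite directions were required instead.

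Chance was excluded for the comparisons of states, since 1 of 35 splits of the 8 condition values gave as many called genes, the real split, in each of the 5. Without a hairpin term the real counts were 7988 (day 7 against growing), 7472 (day 3 against growing), 5942 (quiescent against growing), 9389 (day 7 against quiescent) and 2055 (day 7 against day 3), and the highest of the other splits gave 0, 0, 0, 0 and 1. For the hairpins over the states the same splits, made without a state term, were governed by the states. As many genes as in the real split were found in 35 of 35 splits for shJarid1a and shtandem (real 0, highest other 6558 and 6168), and in 3 of 35 for shJarid1b (real 1, highest other 6237), and none of these counts decides anything about the hairpins. Hairpin labels swapped within states gave as many genes in 1 of 8 swaps for each hairpin (real 1, 1 and 3, highest other 0), too few for a share under 0.05. For shtandem against the single hairpins 2 of 100 splits without a state term gave as many genes (real 1, highest other 557), which decides nothing either, since the split with most genes was uneven over the states. With a state term and the lines swapped within states, 3 of 81 choices gave as many genes (real 1, highest other 1). That share was under 0.05 but cannot exclude chance. The choices include shJarid1a or shJarid1b taken in all states, where the hairpin truly lowers its target. The count was also 1 gene, and 2 other choices reached it too. In the fit of the 16 condition values the count was 0 by limma without any 1 of the states (615 to 782 genes at an unadjusted p under 0.05).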

How the results depend on the processing

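The fits without the 4 narrow arrays or with the interquartile range as a covariate were chosen only after the data were examined. Of 193 counts of called genes under another setting, 133 were within 1.5 times the reported count and 60 were beyond it, and the cause was not tested except where fewer arrays were used. With shLuc alone, which uses fewer arrays, the state counts were 3320 (day 7 against growing), 2332 (day 3 against growing), 732 (quiescent against growing), 4854 (day 7 against quiescent) and 101 (day 7 against day 3). In that fit 112 of 387 named gene calls were lost and 1 reversed, TIE1 in quiescent against growing cells (-0.25, against 0.07131 with adjusted p = 0.962). Without 1 hairpin line the count of day 7 against day 3 was 1668 to 2812. Without 1 state the counts over the states were 2 to 5 (shJarid1a), 1 to 1 (shJarid1b), 4 to 10 (shtandem) and 0 to 0 (shtandem against the single hairpins). Without 1 day 7 array they were 1 to 4 (shJarid1a), 1 to 8 (shJarid1b) and 0 to 14 (shtandem) at day 7, and 0 to 1 for the interaction with growing cells. A filter at log2 above 6 gave 30 genes for shJarid1a over the states. With limma-trend the counts were 4, 15 and 31 at day 7, 94 and 26 for shJarid1a and shJarid1b over the states, 2 for shtandem against the single hairpins and 2 for the interaction with quiescent cells. With all 20 arrays entered separately they were 32, 18, 66 and 0 over the states. With the replicate number as a block they were 25, 38 and 63 at day 7, but differences between replicates correlated across genes from -0.0493 to 0.629 between hairpins, over 0.1 in 4 of 6 pairs of hairpins and not in the other 2, so the numbers were not taken to pair the arrays. Without the narrow arrays 2 genes passed for shJarid1b at day 7, and 4, 4, 12 and 0 over the states, while the state counts stayed within 1.5 times (8969, 7157, 6351, 9608 and 2092). KDM5B with shtandem at day 7 was then no longer called (-1.03, adjusted p = 0.135), so 7 of 8 target calls were kept. With the range as a covariate 6 genes passed for shJarid1a at day 7, 18 for shtandem over the states and 3 for shtandem against the single hairpins. With an estimated correlation 2, 2, 1, 4 and 0 lists passed in the state comparisons, in the order above with day 7 against day 3 last, against 11, 12, 12, 9 and 12, and 0 in each of the 9 hairpin and interaction comparisons. With the mean of all probe sets 1 list passed for shtandem over the states, against 4. Without the narrow arrays 6 passed for shtandem at day 7, against 3, and 2 for shtandem against the single hairpins, against 9. Of 432 named gene calls, 432 were kept without a filter and with limma-trend, 431 with the mean of probe sets, 427 with centred arrays, 394 without the narrow arrays and 425 with the covariate. A comparison with other probe sets of KDM5A and KDM5B could not be made, since each had 1. The filter at log2 4 removed only 538 of 18404 genes, and the lower quartile of the arrays was 4.825 to 4.927. Genes near the background signal may therefore remain among those tested.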

Other observations

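The gene families and clock genes here, and their tests, were chosen after the data were examined, except that the predictions for the clock genes were written before their test. The protocadherin beta genes, cell adhesion genes that lie side by side in a cluster, rose in 15 of 16 members in quiescent against growing cells (median 0.95, adjusted p = 1.03e-12, and adjusted p = 0.00904 with an estimated correlation), with PCDHB10 at 1.67 and PCDHB9 at 1.36. At day 7 of senescence 13 fell (median -0.82, adjusted p = 2.89e-06, and adjusted p = 0.0511 with an estimated correlation), with PCDHB14 at -1.47, PCDHB10 at -1.39 and PCDHB9 at -1.05. At day 3, 14 fell (median -0.77, adjusted p = 0.0458 with an estimated correlation), and against quiescent cells 15 fell at day 7 (median -1.80, adjusted p = 0.0195 with an estimated correlation). With shJarid1a over the states 15 of 16 were higher and 2 passed, PCDHB15 (0.55, adjusted p = 0.00334) and PCDHB16 (0.49, adjusted p = 0.0174), with a median of 0.26 (adjusted p = 1.64e-10, and adjusted p = 0.0161 with an estimated correlation). The median was 0.11 with shJarid1b (13 higher, adjusted p = 0.226 with an estimated correlation) and 0.11 with shtandem (11 higher, adjusted p = 0.681 with an estimated correlation). At day 7 alone the medians were alike, at 0.263 with shJarid1a, 0.225 with shJarid1b and 0.269 with shtandem. None passed there with an estimated correlation (adjusted p = 0.398, 0.655 and 0.5). These genes resemble each other in sequence, and cross-hybridisation between them was not tested.

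Replication-dependent histone genes fell in 42 of 55 at day 7 (median -1.03, adjusted p = 0.0342 with an estimated correlation), in 42 at day 3 (median -0.84, adjusted p = 0.0458 with an estimated correlation) and in 41 in quiescence (median -0.57, adjusted p = 0.0178 with an estimated correlation), each against growing cells. In these comparisons 7, 9 and 2 rose, among them H4C8 (1.56 at day 7, 1.86 at day 3) and H2AC25 (0.97 and 1.41). The linker histone gene H1-4 fell by 3.92 at day 7, by 2.23 at day 3 and by 0.49 in quiescence. Of 27 late cornified envelope and SPRR genes, known from skin, 13 rose at day 7 (median 0.30, adjusted p = 5.66e-06, and adjusted p = 0.13 with an estimated correlation), including LCE2C (4.60), LCE1F (3.98) and LCE3D (3.43). Of 165 small nucleolar and Cajal body RNA genes 94 rose and 11 fell at day 7 against growing cells (median 0.32, adjusted p = 0.289 with an estimated correlation), and 59 rose and 1 fell against day 3 (median 0.24, adjusted p = 0.111 with an estimated correlation). These genes were low in the 4 arrays of narrow range, 2 of 4 at day 3 and 2 of 8 at day 7, and without those arrays 108 rose and 9 fell against growing cells (median 0.38, adjusted p = 0.146 with an estimated correlation) and 46 rose and none fell against day 3 (median 0.25, adjusted p = 0.0933 with an estimated correlation). Whether probe sets of the small RNA, microRNA and histone genes, here and above, measured mature RNAs or other transcripts of these loci was not tested. Their changes are therefore changes of signal and may not be changes of the mature RNAs. Of 433 zinc finger genes named ZNF, 175 rose and 13 fell in quiescence (median 0.18, adjusted p = 0.136 with an estimated correlation). None of the other 7 families passed with an estimated correlation in any comparison. At day 7 against growing cells they were clade B serpins (6 of 10 rose and 2 fell, adjusted p = 0.289 with an estimated correlation), the protocadherin gamma cluster (1 of 1 fell, 0.328), HOX clusters (3 of 27 rose and 3 fell, 0.974), metallothioneins (2 of 8 rose, 0.289), claudins (3 of 22 rose and 1 fell, 0.974), GABA-A receptor subunits (3 of 12 fell and 1 rose, 0.974) and aldehyde dehydrogenases (8 of 19 fell and 1 rose, 0.387).

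Clock genes of the PER and NR1D arm were lower at day 7 than at day 3 of senescence, with a median of -0.88 over 11 genes, 9 of which passed the test. NR1D1 stood at 8.17 in growing cells, 10.2 at day 3 and 8.47 at day 7, PER1 at 7.20, 8.41 and 7.26, and CIART at 6.87, 8.08 and 5.90, while CRY2 and TEF did not pass. Another phase of the circadian clock at harvest was a candidate explanation. The opposite arm (BMAL1, NPAS2, CLOCK and NFIL3) had a median change of -0.1094 (-0.339 to 0.0412 over the lines), where the prediction was above 0.2 on average. Of this arm NFIL3 fell by 0.36 (adjusted p = 8.8e-04), and BMAL1 (-0.09) and CLOCK (-0.15) did not pass. NPAS2 rose by 0.14 in 4 of 4 lines, the predicted direction, without passing (adjusted p = 0.112). By that prediction the median argues against another phase as the whole cause, but it rests on 4 genes and cannot settle the question. The arrays with a narrow spread of values were argued against, since without them the median was -0.8212 (-1.05 to -0.784). The hours of harvest are not given in the sources used here, and no explanation from the groups of the design was tested.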
